A study of Mus musculus with 4 samples.

How the data were processed

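Total RNA of lung tumours from 4 samples was labelled with Cy3 from 100 ng of RNA and hybridised to 1-colour Agilent arrays, per the labels' protocols. The samples were grouped by the CD109 genotype in the labels, 2 CD109+/+ and 2 CD109-/-. Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 12.1.0.3. These files hold intensity values on a linear scale. The processed signal among them was background-subtracted, detrended across the array and kept above a floor, per the file headers, and was not scaled between arrays. A further table deposited by the authors holds processed intensity values of the same arrays, also linear. Each of its columns equalled that array's processed signal times 1 constant (1.19, 1.21, 1.04 and 1.08 for CD109+/+ replicates 1 and 2 and CD109-/- replicates 1 and 2), and the rule behind the constants is not given in the sources used here. The medians of its columns were 58.8, 76.1, 59.5 and 69.2, its values were not centred, and it was used as an alternative only.

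The arrays held 59305 spots without controls, standing for 56605 probes. Spots with an outlier mark (58, 71, 66 and 73 per array) were left out, and spots of 1 probe were averaged. Values were log2 of the processed signal minus each array's 75th percentile of it. A probe was tested when it was well above background on both arrays of at least 1 genotype, which left 35777 probes. Probes were named through their accession in a RefSeq gene table of assembly GRCm38.p6, leaving out versions and accessions shared between genes. A symbol was found for 34566 probes of 23787 genes, and 22039 probes stayed without a symbol and entered only the counts by probe. The array files use another genome build than this table, so no coordinates were used beyond the order of genes. A gene was represented by its tested probe with the highest mean over the 4 arrays, giving 16443 genes, and further probes are given for named genes where they differed most. For a probe not well above background on both arrays of 1 genotype only a bound can be given. It is the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. The p-values of such probes were computed from their measured values and not from the bound.

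Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided and without covariates, on all 4 arrays (2 residual degrees of freedom and 2.54 prior degrees of freedom in the fit by gene). Benjamini-Hochberg adjustment ran over all probes or all genes with a threshold of 0.05. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 39 lists, and again with the correlation estimated from the data and with fry. Fry tests whether a list's genes moved one way on balance and does not compare them with other genes. The estimated correlation rests on 2 residual degrees of freedom, and so does the reference distribution of that form of camera. The lists hold 922 entries, of which 850 were measured, and some genes stand in several lists. Setting members not well above background in 1 genotype at their bound left every list's median the same to 2 decimals.

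The genes named were fixed by rule before the data were examined, as were the lists, the tests and the alternatives, except where stated. The rule took Cd109, then in each direction the 12 non-overlapping genes past the threshold with the largest difference or, where fewer than 10 passed, up to 10 with the lowest unadjusted p among those differing by at least 1 on the log2 scale. Predicted genes, genes without a symbol and the sex-linked genes were left out of that ranking. From each list past its threshold it took the 4 members with the largest moderated t in the list's direction. From the TGF-beta, EMT, epithelial, matrix, protease and JAK-STAT3 lists it took the 3 members with the largest absolute moderated t, and in addition a few fixed genes, among them Tgfb1, Ltbp1 and Smad7. It named 111 genes in all, of which a few are not reported here.

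Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the authors' processed values, no filter on dim probes, a filter asking for signal on all 4 arrays, a mean-variance trend, the replicate number as a block, sex as a covariate, the mean of a gene's probes, other thresholds and leaving out each array in turn. Normexp had been planned on the mean spot signal, which is not given in the sources used here, and was run on the median spot and background signals instead. Where 1 array was left out, the lone array of that genotype was assumed to vary like the others. All 4 arrays lay on 1 slide and were scanned in 1 session, so neither could act as a batch and no slide block was run. Lists without members that stand in another list were added after the data were seen.

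The procedure was tested on simulated data drawn for the 16443 genes of this comparison, with 200 genes changed in each of 20 draws. Recovery at an adjusted p under 0.05 was 0.3% for a log2 change of 1, 9.3% for 2, 80.8% for 4 and 93.0% for 6, with a mean of 4.95 false calls per draw. The changed genes were split evenly over these sizes, and strong changes ease the adjustment for the rest. Recovery may therefore be lower in data with fewer strong changes. Of unchanged genes 4.98% had an unadjusted p under 0.05. The draws took independent genes with variances from the fitted model, so this share follows from the simulation's construction and does not check the real arrays. A list shifted by 0.5 was called in 100% of draws, and unchanged lists of independent genes were called 0 times. Estimated correlations in the real lists reached 0.736 (ciliated cell markers). The simulation therefore gives neither the recovery nor the false calls of lists of correlated genes.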

Results

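Gene expression was measured in lung tumours of KP mice, a model of lung adenocarcinoma in which tumours are started by Cre recombinase. Adenovirus carrying Cre had been delivered into the trachea, and RNA was taken 88 to 92 days later. The 4 samples comprised 2 from CD109+/+ mice, both female, and 2 from CD109-/- mice, of which replicate 1 was male and replicate 2 female. Each sample was hybridised to 1 single-colour Agilent array. The 75th percentile of the signal lay at 557, 669, 677 and 688 on CD109+/+ replicates 1 and 2 and CD109-/- replicates 1 and 2. On the same arrays 64.3%, 67.0%, 65.0% and 65.3% of the spots were well above background, and 0 spots were saturated. Between arrays, CD109-/- replicate 2 was as close to CD109+/+ replicate 2 (Pearson r = 0.982) as the CD109+/+ arrays were to each other (0.982), with r = 0.969 to CD109+/+ replicate 1, whereas CD109-/- replicate 1, the only male, had r of 0.971, 0.968 and 0.968 to the others. The labels name a mouse for each sample but do not state that replicates were separate animals, so p-values measured only the spread between these samples. The number of arrays limits the precision of every value, and with 2 against 2 an exact two-sided permutation test of a single gene cannot give a p below 0.333. All log2 values are relative to each array's 75th percentile, differences are CD109-/- minus CD109+/+, and errors of differences are limma's standard errors (SE, n = 2 per genotype).

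The targeted gene was read first. CD109 is a membrane-anchored glycoprotein of the alpha-2-macroglobulin family that can act as a TGF-beta co-receptor. Its single named probe gave log2 signals of -3.70 and -4.66 in CD109+/+ tumours, a mean of -4.18 ± 0.68 (SD, n = 2). On both CD109-/- arrays the Cd109 probe was not well above background, with measured values of -7.98 and -7.87. Cd109 signal was therefore at least 2.92-fold higher in CD109+/+ tumours, and the fit gave limma's adjusted p = 0.299 over all genes. The part of the transcript under this probe, and whether the deletion removed it, were not examined, so the low signal follows the labels without showing which part of the gene was lost. Xist, the RNA that silences an X chromosome in females, had log2 signals of 0.82, 0.52 and 0.67 on the arrays labelled female and -7.98 on the array labelled male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background only on the array labelled male.

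The main comparison asked which genes and gene sets differed with CD109 deficiency. No single gene passed the threshold, and those with the lowest p are given as values. Among those with higher values in CD109-/- tumours were the B cell attracting chemokine Cxcl13 and the cytokine Tnfsf11 (RANKL). Cxcl13 was at least 7.48-fold higher and Tnfsf11 at least 1.97-fold higher, since neither was well above background on the CD109+/+ arrays. Ccl8, a chemokine for monocytes and lymphocytes, differed by 2.27 ± 0.23 on the log2 scale. The xenobiotic-metabolising cytochrome P450 genes Cyp2b9 and Cyp2b10 differed by 2.30 ± 0.21 and 2.20 ± 0.21, and a further probe of Cyp2b10 gave 2.15. Pcolce2, which enhances procollagen processing, differed by 2.65 ± 0.29. The X-linked paralogs Xlr3b and Xlr4a differed by 1.95 ± 0.21 and 2.09 ± 0.22, with a further Xlr4a probe at 1.26, and cross-hybridisation between members of this family cannot be ruled out. Lrat, which esterifies retinol, was at least 3.98-fold higher. The zinc finger gene Bnc2 was at least 1.31-fold higher, and without the filter on dim probes another probe stood for Bnc2 and gave -0.09.

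Among genes with lower values in CD109-/- tumours, Nrip2 was at least 6.69-fold lower and the lipid droplet gene Fitm1 at least 1.86-fold lower, neither being well above background on the CD109-/- arrays. Rps6ka6, a kinase of the RSK family, differed by -3.57 ± 0.24 (further probe -3.01) and was well above background on 1 of the 2 CD109-/- arrays. The gel-forming mucin Muc2 differed by -2.98 ± 0.21 and the growth factor Egf by -2.63 ± 0.27. Several genes best known from liver also stood here. These were Igfals, which carries IGF in the circulation (-2.52 ± 0.27), Mst1, which encodes macrophage-stimulating protein (-2.37 ± 0.22), the urea cycle enzyme Otc (-2.05 ± 0.21) and Fgl1 (-1.89 ± 0.23).

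**Figure D1:**
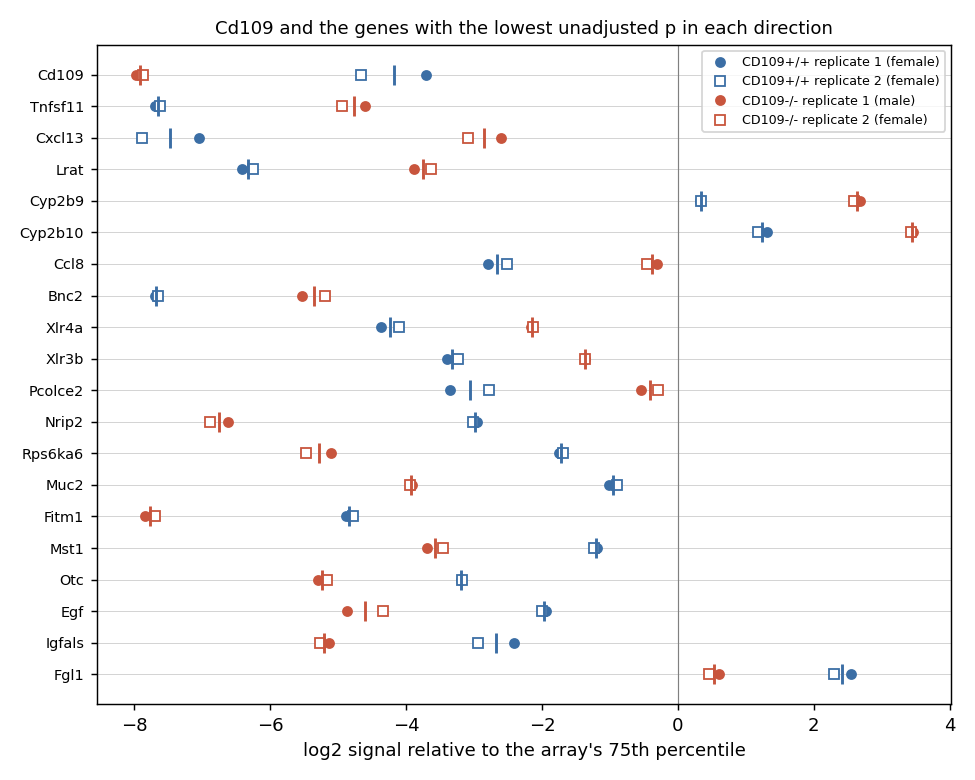
Log2 signal relative to each array's 75th percentile (horizontal axis) on each of the 4 arrays for Cd109 and the 19 other genes with the lowest unadjusted p in either direction; points are arrays and vertical ticks are means of 2 arrays. None of these genes passed the threshold after adjustment.

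Of the 16443 genes tested, 0 passed limma's Benjamini-Hochberg threshold of 0.05, and the lowest adjusted p was 0.266. At an unadjusted p under 0.05 there were 1219 genes, 822 with higher and 397 with lower values in CD109-/- tumours, against 822 that chance would give. Of these, 433 differed upward and 195 downward by at least 1 on the log2 scale. Splits of the same arrays that mix the genotypes gave 1315 and 179 genes at an unadjusted p under 0.05, so the count of 1219 alone does not set the genotypes apart. The 2 genotypes did not overlap in 38.6% of genes, against 33.3% by chance. By probe, 0 of 35777 passed (lowest adjusted p = 0.288 with limma), and 2438 had an unadjusted p under 0.05. Of these probes 1387 were higher and 1051 lower, against 1789 that chance would give. Probes whose genotypes did not overlap leaned the other way, with 5891 higher and 7599 lower. Without CD109-/- replicate 2, limma called 2 probes and 0 genes at an adjusted p under 0.05, and 1929 genes had an unadjusted p under 0.05, of which 974 (50.5%) were higher, so that the excess of higher genes was gone. That count was 553 without CD109+/+ replicate 1.

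Gene lists fixed before the data were examined were then tested as groups. Of 39 lists, 21 passed camera's threshold with its preset correlation of 0.01, 19 higher and 2 lower in CD109-/- tumours. Splits of the same arrays that mix the genotypes gave 17 calls (both replicates 1 against both replicates 2) and 6 calls with this test. The number of calls alone therefore does not set the genotypes apart. In the comparison of genotypes 0 lists passed with an estimated correlation (4 at an unadjusted p under 0.05, lowest adjusted p = 0.327), and with fry 0 passed (6 at an unadjusted p under 0.05, lowest adjusted p = 0.157). The macrophage, T and NK cell, fibroblast and matrix lists had estimated correlations of 0.0018, -0.034, -0.028 and -0.011, below the preset. Correlation above the preset therefore did not end the calls of these lists. That form of camera takes its p from 2 degrees of freedom, which leaves little room to pass after adjustment over 39 lists. Its adjusted p-values below therefore do not by themselves show that a call failed for correlation. Fry's mixed test, read after the data were seen, counts members moving either way and does not compare them with other genes. It passed 5 lists, TGF-beta ligands, receptors and regulators (fry mixed adjusted p = 0.000117), matrix (0.000506), macrophages (0.0136), cytokines (0.0392) and T and NK cells (0.0448). In the TGF-beta regulator list 2 of 29 members had an unadjusted p under 0.05 with limma, near the share over all genes (1219 of 16443). No list had a member past the threshold over all genes, so the members below are named with their values only. Without CD109-/- replicate 2 camera called 13 lists, and 5 lists were called whichever array was left out.

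Over all 4 arrays the list with the largest median shift was inflammatory cytokines and chemokines, which was higher in CD109-/- tumours with a median log2 difference of 1.02 (camera adjusted p = 5.0e-10). Its call was lost at adjusted p = 0.573 with an estimated correlation. Of 30 measured members 28 had higher values, and 5 passed when adjusted over the list alone, namely Cxcl13, Ccl8, Il6, Ccl11 and Ccl7, the last named after its value was seen. Il6, a cytokine that signals through STAT3, differed by 1.82 ± 0.35, and a further Il6 probe gave 2.68. The eosinophil chemokine Ccl11 differed by 1.41 ± 0.29. The list's medians by array were -0.54 and -0.55 in CD109+/+ tumours and 0.99 and 0.07 in CD109-/- tumours. Without CD109-/- replicate 1 the median shift was 0.59 (camera adjusted p = 0.000296), smaller than that of several other lists, such as ciliated cell markers at 1.01.

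Markers of macrophages and monocytes were higher in CD109-/- tumours, with a median of 0.56 and higher values in 23 of 24 members (camera adjusted p = 1.7e-08). This became adjusted p = 0.327 with an estimated correlation, as did the T and NK cell list. Adjusted over the list alone, 2 members passed, Cd163 and Mrc1. The scavenger receptor gene Cd163 was at least 3.39-fold higher, being not well above background on the CD109+/+ arrays. The mannose receptor gene Mrc1 differed by 1.21 ± 0.22, the integrin gene Itgax by 0.86 ± 0.21 (2 further probes 0.44 and 0.93) and the macrophage marker gene Adgre1 by 0.94 ± 0.25. Markers of T and NK cells were higher with a median of 0.80 and higher values in 18 of 20 members (camera adjusted p = 1.1e-06), and 0.47 with normexp. The T cell receptor complex genes Cd3d and Cd3g differed by 1.63 ± 0.30 and 1.54 ± 0.32 and the NK receptor gene Klrd1 by 1.57 ± 0.30. Of the 6 members that passed when adjusted over the list alone, these 3 were named by the rule, and Cd6 and Il7r after their values were seen.

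Stromal and matrix lists shifted in the same direction. Markers of fibroblasts and smooth muscle were higher in CD109-/- tumours with a median of 0.62 and higher values in 20 of 23 members (camera adjusted p = 3.0e-06; adjusted p = 0.327 with an estimated correlation). The platelet-derived growth factor receptor gene Pdgfra differed by 1.77 ± 0.37 and its second probe by 1.52, Wnt2 by 1.57 ± 0.27 and the methyltransferase gene Inmt by 1.80 ± 0.48. Collagens and extracellular matrix genes were higher with a median of 0.48 and higher values in 29 of 34 members (camera adjusted p = 3.1e-05; adjusted p = 0.327 with an estimated correlation). The fibrillar collagen gene Col3a1 differed by 1.27 ± 0.22, the proteoglycan gene Lum by 1.71 ± 0.22, the collagen crosslinking enzyme gene Lox by 1.08 ± 0.28 and Fbln1 by 0.86 ± 0.24, with a further Fbln1 probe at 2.00. Adjusted over the list alone, 2 genes passed in the fibroblast list (Lum and Wnt2) and 2 in the matrix list (Col3a1 and Lum). Of the 34 matrix genes, 13 also stood in another list. The matrix medians by array were -0.01 and -0.29 in CD109+/+ tumours and 0.22 and 0.26 in CD109-/- tumours, and the matrix shift was 0.30 without CD109+/+ replicate 2.

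The study linked CD109 to TGF-beta signalling, so the TGF-beta lists were read next, and neither passed camera's threshold. TGF-beta target genes had a median difference of 0.20, with higher values in 20 of 31 members and 0 members passing when adjusted over the list alone (camera adjusted p = 0.0682; adjusted p = 0.727 with an estimated correlation). The members went both ways. Col3a1 stood at 1.27 ± 0.22 and the matrix protein gene Tgfbi at 0.95 ± 0.29, whereas the collagen-binding integrin gene Itga11 stood at -2.17 ± 0.59. The inhibitory Smad7 differed by -0.12 ± 0.29, within its error, and its further probe by -0.28. Of the 31 members 21 also stood in another list, many of them matrix genes, and the matrix, fibroblast and macrophage lists were higher on the same arrays. Without CD109+/+ replicate 1 the list was called at a median of 0.38 (camera adjusted p = 0.000558) and without CD109-/- replicate 2 at 0.32 (camera adjusted p = 0.00894). Without CD109+/+ replicate 2 the median was -0.07 and without CD109-/- replicate 1, which leaves females only, -0.04.

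TGF-beta ligands, receptors and regulators had a median of 0.15 with higher values in 18 of 29 members, and 0 passed when adjusted over the list alone (camera adjusted p = 0.183; adjusted p = 0.573 with an estimated correlation), although fry's mixed test passed it. Among its members 2 had an unadjusted p under 0.05 with limma. Tgfb1 itself differed by 0.46 ± 0.29, and its further probe by 0.19. Ltbp1, which holds latent TGF-beta in the matrix, differed by 0.65 ± 0.22, Nrros, which does so on myeloid cells, by 0.86 ± 0.23, and the ubiquitin ligase gene Smurf1 by -0.86 ± 0.33. The median of this list was 0.01 without CD109+/+ replicate 2 and 0.09 without CD109-/- replicate 1. The BMP pathway list was not called (camera adjusted p = 0.622), and its median of -0.09 and mean of 0.14 differed in sign while camera's direction was upward. Its median was 0.11 without CD109-/- replicate 1.

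The lists of cell state and invasion gave mixed values. EMT and mesenchymal state was higher in CD109-/- tumours with a median of 0.27 and higher values in 13 of 18 members (camera adjusted p = 0.034; adjusted p = 0.573 with an estimated correlation). The EMT transcription factor gene Zeb2 differed by 0.95 ± 0.21, although its 3 other probes ranged from -0.21 to 0.58. With normexp the EMT median was 0.17. Of the 18 EMT members 6 also stood in another list, and the fibroblast and matrix lists were higher on the same arrays. On members found in 1 list only the EMT median was 0.23 and the call was lost (camera adjusted p = 0.173). The receptor kinase gene Axl differed by 0.71 ± 0.22, the transglutaminase gene Tgm2 by 0.71 ± 0.24 and the N-cadherin gene Cdh2, a mesenchymal marker, by -1.87 ± 0.52. The EMT call was lost without CD109+/+ replicate 2 (median 0.42, camera adjusted p = 0.264), CD109-/- replicate 1 (0.45, 0.0994) or CD109-/- replicate 2 (0.39, 0.0733), and the median was 0.47 without CD109+/+ replicate 1. Epithelial state was not called (median -0.07, 16 of 25 members with lower values, camera adjusted p = 0.21), with Spint2 at -0.52 ± 0.28, the tight junction gene Ocln at -0.48 ± 0.30 and the keratin gene Krt18 at -0.46 ± 0.39. Without CD109-/- replicate 1 the epithelial list was called lower at a median of -0.35 (camera adjusted p = 0.00153), and without CD109-/- replicate 2 its median was 0.24. In the EMT and the epithelial list 0 members passed when adjusted over the list alone.

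Extracellular proteases and inhibitors were higher with a median of 0.28 and higher values in 21 of 31 members (camera adjusted p = 0.0315; adjusted p = 0.573 with an estimated correlation). The matrix metalloproteinase genes Mmp8, Mmp2 and Mmp3 differed by 1.39 ± 0.29, 1.13 ± 0.26 and 2.47 ± 0.68, and Ctss, a cathepsin gene of antigen-presenting cells, by 0.75 ± 0.24. The call was lost without CD109+/+ replicate 2 (median 0.21, camera adjusted p = 0.32) and without CD109-/- replicate 1 (median 0.07, camera adjusted p = 0.566), and the median was 0.44 without CD109+/+ replicate 1. JAK-STAT3 pathway and targets were higher with a median of 0.27 and higher values in 21 of 29 members (camera adjusted p = 0.00295; adjusted p = 0.521 with an estimated correlation). Besides Il6, the acute-phase gene Saa3 differed by 2.90 ± 0.80, the transcription factor gene Cebpb by 0.84 ± 0.22 and Steap4 by 0.63 ± 0.23. Reg3g, an antimicrobial lectin gene, went the other way and was at least 2.28-fold lower, not being well above background on the CD109-/- arrays. This call was lost without CD109-/- replicate 1 (median 0.36, camera adjusted p = 0.153), and the median was 0.41 without CD109+/+ replicate 1 and 0.42 without CD109-/- replicate 2. Both lists had 0 members passing when adjusted over the list alone.

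Further immune lists were called higher. Antigen presentation had a median of 0.58 and higher values in 18 of 19 members (camera adjusted p = 5.8e-05; adjusted p = 0.589 with an estimated correlation). The MHC genes H2-Oa, H2-Ob and H2-D1 differed by 1.21 ± 0.37, 0.66 ± 0.23 and 0.75 ± 0.32, and Nlrc5, a transactivator of MHC class I, by 0.97 ± 0.34. The interferon response had a median of 0.48 and higher values in 26 of 28 members (camera adjusted p = 0.000108; adjusted p = 0.600 with an estimated correlation), with Oas2 at 1.14 ± 0.29, the chemokine gene Cxcl9 at 1.05 ± 0.32, and Gbp4 and Gbp5 at 0.90 ± 0.27 and 0.62 ± 0.21. The alpha-2-macroglobulin and complement family had a median of 0.62 and higher values in 13 of 16 members (camera adjusted p = 0.000612; adjusted p = 0.573 with an estimated correlation). The complement gene C2 differed by 1.93 ± 0.33 and the inhibitor gene Serping1 by 1.34 ± 0.28, and both were among the 3 that passed when adjusted over the list alone, whereas Cfb at 0.56 ± 0.22 did not. The antigen presentation call was lost without CD109-/- replicate 2 (median 0.34, camera adjusted p = 0.0754), as was that of the complement family (0.36, 0.062). Without CD109+/+ replicate 1 the interferon call (median 0.15, camera adjusted p = 0.249) and the complement call (0.41, 0.0901) were lost, and antigen presentation had a median of 0.32. The interferon median was 0.77 without CD109+/+ replicate 2.

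Immune checkpoints and suppression had a median of 0.45 and higher values in 12 of 16 members (camera adjusted p = 0.0138; adjusted p = 0.573 with an estimated correlation). Havcr2 (TIM-3), Cd86, Vsir (VISTA) and Pdcd1lg2 (PD-L2) differed by 1.06 ± 0.24, 0.96 ± 0.24, 0.94 ± 0.23 and 0.95 ± 0.28, with further Cd86 probes at 0.47 and 0.99. Neutrophil markers had a median of 0.56 and higher values in 10 of 16 members (camera adjusted p = 0.0382; adjusted p = 0.573 with an estimated correlation). The chemokine receptor genes Cxcr2 and Cxcr1 differed by 1.82 ± 0.66 and 0.77 ± 0.32 and the calprotectin gene S100a9 by 1.28 ± 0.50. Markers of dendritic cells, mast cells and eosinophils had a median of 0.28 and higher values in 8 of 13 members (camera adjusted p = 0.0401; adjusted p = 0.573 with an estimated correlation). Their dendritic members Clec9a, Cd209a, Flt3 and Ccr7 differed by 1.32 ± 0.25, 2.55 ± 0.58, 2.20 ± 0.53 and 0.95 ± 0.24, a further Cd209a probe at 1.10, and Cd209a and Flt3 well above background on 1 of the 2 CD109+/+ arrays, and these 4 passed when adjusted over the list alone. All 3 calls were lost without CD109-/- replicate 1, with camera adjusted p = 0.153 for checkpoints (median 0.40), 0.614 for neutrophils (0.06) and 0.295 for dendritic cells (0.57). The checkpoint and neutrophil calls were lost without CD109+/+ replicate 2, both at camera adjusted p = 0.172 (medians 0.29 and 0.41), and the dendritic median was 0.11. With normexp the checkpoint median was 0.23 and the dendritic one 0.16, and without the filter on dim probes the latter was 0.06. Medians of checkpoints, neutrophils and dendritic cells were 0.73, 0.87 and 0.48 without CD109+/+ replicate 1 and 0.80, 1.05 and 0.51 without CD109-/- replicate 2.

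Other cell types of the lung were also represented among the calls. Endothelial and lymphatic markers were higher with a median of 0.25 and higher values in 18 of 21 members (camera adjusted p = 0.00351; adjusted p = 0.614 with an estimated correlation), with Calcrl at 1.22 ± 0.28, the angiopoietin receptor gene Tek at 0.93 ± 0.23, Plvap at 0.57 ± 0.22 and Ackr1 at 1.34 ± 0.53. Mesothelial and adipocyte markers were higher with a median of 0.65 and higher values in 7 of 10 members (camera adjusted p = 0.0273; adjusted p = 0.573 with an estimated correlation). The mesothelial transcription factor gene Wt1 was at least 3.95-fold higher, Lrrn4 was at least 1.84-fold higher, and Upk1b differed by 0.85 ± 0.47. Wt1 passed when adjusted over the list alone, on measured values not well above background in CD109+/+ tumours. Upk3b differed by 2.21 ± 0.68 and was well above background on 1 of the 2 CD109+/+ arrays. The mesothelial median was 0.42 without CD109+/+ replicate 2, 0.20 with normexp (camera adjusted p = 0.139) and 0.03 when signal was asked on all 4 arrays (0.598). Erythroid markers were higher with a median of 0.64 in 8 of 8 members (camera adjusted p = 0.00055, and adjusted p = 0.573 with an estimated correlation). The globin genes Hbb-bt, Hbb-b2, Hba-a1 and Hba-a2 differed by 0.79 ± 0.24, 0.64 ± 0.22, 0.68 ± 0.27 and 0.67 ± 0.28. Copies within the beta (Hbb) or within the alpha (Hba) group are closely similar, and probes may not tell them apart. Ciliated cell markers were higher with a median of 0.64 and higher values in 13 of 15 members (camera adjusted p = 0.0273; adjusted p = 0.727 with an estimated correlation). The ciliogenesis factor gene Foxj1 differed by 1.95 ± 1.22, Mlf1 by 1.32 ± 0.41, Rsph1 by 1.05 ± 0.66 and Dynlrb2 by 0.64 ± 0.42. All 4 calls were lost without CD109-/- replicate 2, with camera adjusted p = 0.296 for endothelial (median 0.10), 0.11 for mesothelial (0.49), 0.073 for erythroid (0.41) and 0.737 for ciliated markers (0.06). The ciliated call was also lost without CD109+/+ replicate 1 (median 0.15, camera adjusted p = 0.583). Its median was 1.05 without CD109+/+ replicate 2 and 1.01 without CD109-/- replicate 1, and the endothelial median was 0.43 without the latter.

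Only hypoxia and glycolysis and RAS-MAPK output were called lower in CD109-/- tumours. Hypoxia and glycolysis had a median of -0.29 and lower values in 21 of 25 members (camera adjusted p = 0.0223; adjusted p = 0.727 with an estimated correlation). The glycolytic gene Hk2 differed by -0.72 ± 0.30, Bnip3 by -0.64 ± 0.37, Pdk1 by -0.61 ± 0.37 (3 further probes from -0.75 to -0.20) and Ankrd37 by -1.10 ± 0.73. The 2 genotypes overlapped in this list, with medians by array of 0.60 and -0.20 in CD109+/+ and 0.12 and -0.50 in CD109-/- tumours. The shift was 0.02 without CD109+/+ replicate 1 and 0.02 without CD109-/- replicate 2, and the call was lost in both, whereas it was -0.77 without CD109+/+ replicate 2 and -0.66 without CD109-/- replicate 1. RAS-MAPK output had a median of -0.20 and lower values in 17 of 21 members (camera adjusted p = 0.0273; adjusted p = 0.573 with an estimated correlation). The feedback phosphatase gene Dusp4 differed by -0.58 ± 0.25, the ETS factor gene Etv4 by -0.62 ± 0.26, Egr1 by -0.59 ± 0.26 and Epha4 by -0.35 ± 0.21. This call was lost without CD109+/+ replicate 2 (median -0.24, camera adjusted p = 0.102) and without CD109-/- replicate 2 (median -0.12, camera adjusted p = 0.949), and the median was -0.43 without CD109-/- replicate 1. Targets of p53 were called higher with a median of 0.34 and higher values in 14 of 19 members (camera adjusted p = 0.0382; adjusted p = 0.589 with an estimated correlation). Ccng1, Phlda3, Fas and Zmat3 differed by 1.12 ± 0.31, 0.85 ± 0.25, 0.87 ± 0.40 and 0.44 ± 0.22, with a further Fas probe at 0.43. The p53 call was lost without CD109+/+ replicate 2 (median 0.07, camera adjusted p = 0.32) and without CD109-/- replicate 2 (0.33, 0.196). Its median was 0.17 without CD109-/- replicate 1.

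**Figure D2:**
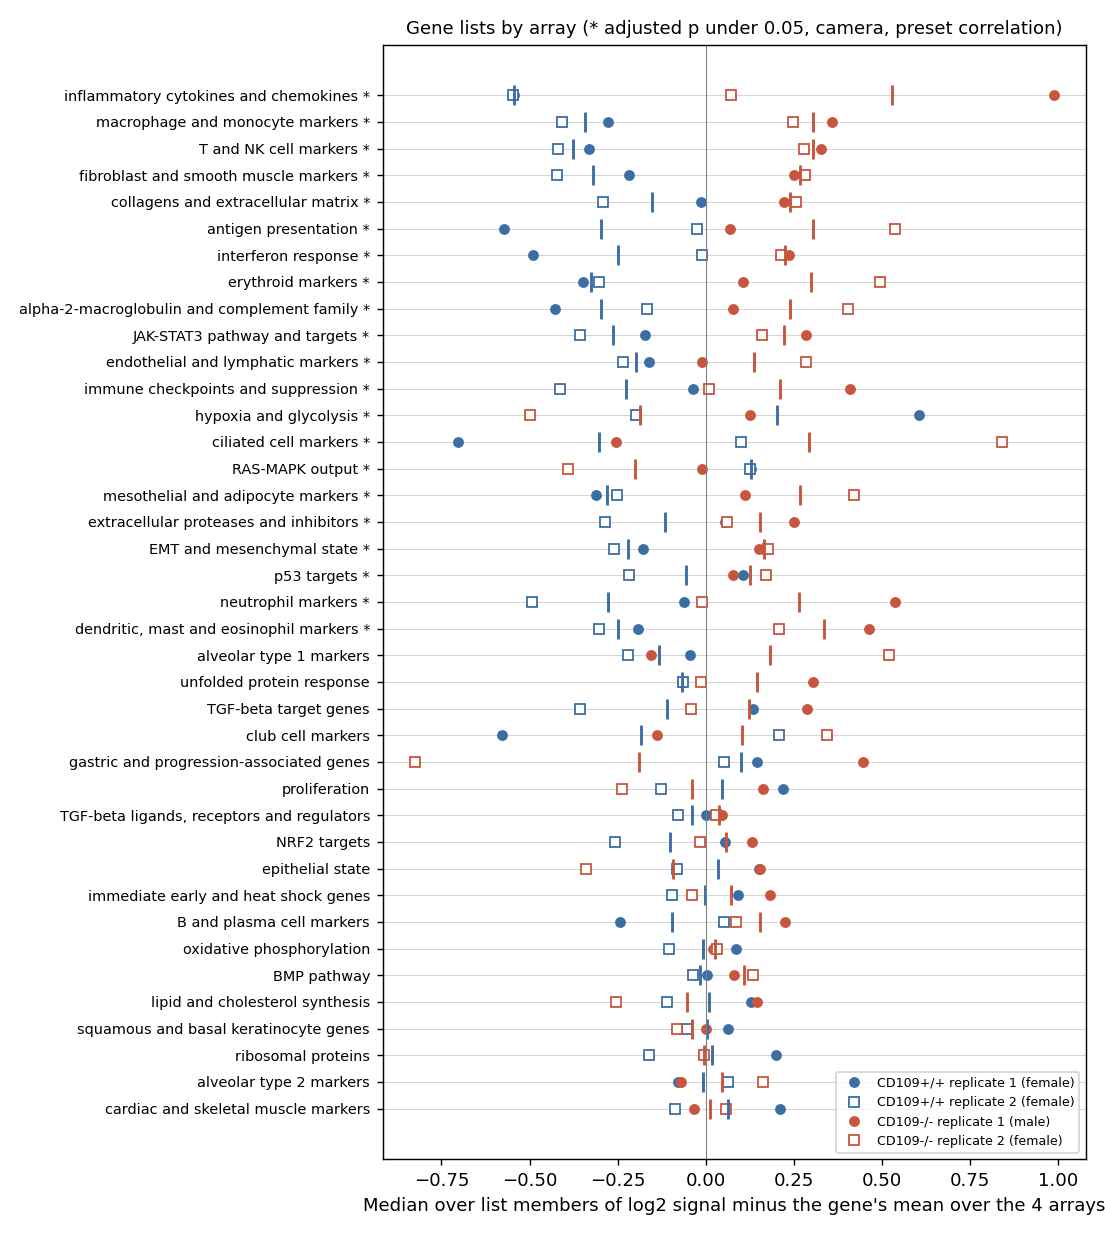
Median over the measured members of each of the 39 gene lists of log2 signal minus the gene's mean over the 4 arrays (horizontal axis), by array; points are arrays, vertical ticks are means of 2 arrays, and an asterisk marks camera's adjusted p under 0.05 with the preset correlation. In 18 of the 21 marked lists both CD109-/- arrays lie on one side of both CD109+/+ arrays, and 0 lists pass with an estimated correlation.

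The remaining lists did not pass. Among markers of lung epithelium, alveolar type 1 cells stood at a median of 0.22 (camera adjusted p = 0.0602), club cells at 0.39 (0.106) and alveolar type 2 cells at -0.00 (0.927), the last with a mean of 0.03 and camera's direction downward. B and plasma cell markers had a median of 0.00 (camera adjusted p = 0.457), with 8 members higher and 7 lower. Adjusted over that list alone 3 genes passed, all named after their values were seen. Jchain and Mzb1, genes of antibody-secreting cells, stood at 2.51 ± 0.42 and 1.87 ± 0.35, and Derl3, a gene of endoplasmic reticulum quality control, at -1.04 ± 0.21. Proliferation had a median of -0.09 and lower values in 25 of 34 members (camera adjusted p = 0.179), and gastric and progression-associated genes had a median of -0.21 (camera adjusted p = 0.179). Both were called lower without CD109-/- replicate 1, at medians of -0.29 (camera adjusted p = 0.000243) and -1.27 (0.000145), whereas without CD109-/- replicate 2 the medians were 0.10 and 0.64. Proliferation was also called lower without CD109+/+ replicate 2 (camera adjusted p = 0.0159).

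In metabolic and stress lists the medians were 0.19 for the unfolded protein response (camera adjusted p = 0.0618), 0.18 for NRF2 targets (0.197), 0.07 for immediate early and heat shock genes (0.447), 0.07 for oxidative phosphorylation (0.581) and -0.04 for lipid and cholesterol synthesis (0.698). Squamous and basal keratinocyte genes stood at -0.08 (camera adjusted p = 0.757), ribosomal proteins at -0.02 (0.868) with a mean of 0.00, and cardiac and skeletal muscle markers at 0.12 (0.927). The call changed when 1 array was left out for several lists. Alveolar type 1 markers were called without CD109+/+ replicate 1 (median 0.33, camera adjusted p = 0.0186) and without CD109-/- replicate 1 (0.55, 0.000876), but stood at 0.14 without CD109+/+ replicate 2 and 0.02 without CD109-/- replicate 2. They were also called with normexp (0.0267) and without the filter on dim probes (0.0393). NRF2 targets were called without CD109+/+ replicate 1 (median 0.31, 0.0353), and their median was 0.05 without CD109-/- replicate 1 and 0.33 without CD109-/- replicate 2. Club cell markers (median 0.68, 0.00628) and B and plasma cell markers (0.51, 0.0295) were called without CD109+/+ replicate 2. The club cell median was -0.01 without CD109+/+ replicate 1 and 0.58 without CD109-/- replicate 1, and the list was called when signal was asked on all 4 arrays (0.0193). The unfolded protein response was called without CD109-/- replicate 2 (median 0.38, 0.0165) but stood at 0.08 without CD109-/- replicate 1 (0.856). This list was also called higher with normexp (0.0162), without the filter on dim probes (0.0393) and with a variance trend (0.043). Ribosomal proteins were called higher without CD109+/+ replicate 1 (0.0353) and lower without CD109+/+ replicate 2 (0.029). Apart from B and plasma cell markers, 0 members of the lists in these last 2 paragraphs passed when adjusted over the list alone.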

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

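Restricting lists to members found in 1 list only was chosen after the result was seen, and the other settings were planned. No gene passed limma's adjusted threshold in any setting, and the 0 probes called became 2 at most (lowest 0, highest 2) when 1 array was left out, without CD109-/- replicate 2. At an unadjusted p under 0.05 there were 2438 probes. By gene that count was 1219, and it ranged from 553 (without CD109+/+ replicate 1) to 1929 (without CD109-/- replicate 2) with 1 array left out. Cd109 had the lower value in CD109-/- tumours in every setting that kept its probe, and as its probe was not well above background there, only the bound is given as a size.

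The 21 list calls became 0 with an estimated correlation and 0 with fry, ranged from 13 to 21 with 1 array left out, and otherwise lay between 18 and 23. Sex as a covariate gave the same estimates as leaving out CD109-/- replicate 1, since that array is the only male. With the replicate block 1898 genes had an unadjusted p under 0.05 and 18 lists were called. The correlation of same-numbered deviations was 0.347, but there are only 2 pairs and the labels do not say what a number marks, so the samples were not treated as paired. The 5 lists of cytokines, macrophages, T and NK cells, fibroblasts and matrix were called in all 14 settings that used camera with the preset correlation. Quantile normalization ended the calls of proteases and p53 targets, normexp that of mesothelial markers, no filter that of neutrophils, and the filter on all 4 arrays those of mesothelial and dendritic markers. The replicate block ended those of EMT, proteases and dendritic markers. Members in 1 list only ended EMT (camera adjusted p = 0.173), proteases (0.0589), neutrophils (0.184) and dendritic markers (0.0924), and added alveolar type 1 and club cell markers.

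The TGF-beta target list, not called, was called at 0.19 with normexp, 0.18 with the authors' values, 0.20 without the filter and 0.23 with the mean of a gene's probes. Leaving out 1 array gave -0.0724 to 0.38. Restricted to members found in no other list its median was -0.02.

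Camera's direction, or a gene's, turned in these cases, all with the median given and the cause not tested. With normexp it turned for alveolar type 2 (0.0363), BMP (-0.0264), cardiac and skeletal muscle (-0.0316) and ribosomal (-0.00560) lists. With quantile normalization it turned for ribosomal proteins (0.0187), and with the mean of a gene's probes for ribosomal proteins (0.00920) and alveolar type 2 markers (0.0408). Fry turned ribosomal proteins (-0.0178). Without the filter it turned for Bnc2 (-0.0949), alveolar type 2 markers (-0.00477) and squamous genes (-0.0146), and with signal on all 4 arrays for BMP (-0.15) and muscle (0.0235). The replicate block turned alveolar type 2 markers (-0.00477), and sex as a covariate turned them (0.22) and the immediate early genes (-0.0637).

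With 1 array left out, the ranges for lists that turned in at least 1 case were -0.0637 to 0.22 for alveolar type 2 markers, -0.22 to 0.14 for muscle, 0.0559 to 1.05 for ciliated cells and -0.35 to 0.24 for the epithelial list. They were -1.27 to 0.64 for gastric genes, -0.77 to 0.0216 for hypoxia, -0.0637 to 0.27 for immediate early genes and -0.26 to 0.10 for lipid synthesis. For oxidative phosphorylation they were -0.10 to 0.14, for proliferation -0.29 to 0.10, for ribosomal proteins -0.21 to 0.16 and for squamous genes -0.22 to 0.22. Smad7 ranged from -0.40 to 0.16, turning without CD109-/- replicate 2.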

Other observations

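The tests on how the 4 arrays split, on single CD109-/- arrays, on the share of tumour cells and on the Xlr genes were chosen after the result was seen, and those on neighbours of Cd109 and on hepatocyte genes were set before theirs was. Liver-expressed genes such as Igfals, Otc and Mst1 stood among the genes with the lowest p in the lower direction, so a separate list of 50 genes known from hepatocytes, none of them named in the report, was written and then tested. Of 38 measured, 26 had lower and 12 higher values in CD109-/- tumours, with a median log2 difference of -0.38 (camera p = 0.0309 with the preset correlation, p = 0.136 with an estimated correlation). The medians by array were 0.04 and 0.11 in CD109+/+ and -0.17 and 0.02 in CD109-/- tumours, so the genotypes were separated by little. The liver theme was taken from the same 4 arrays, so this is no independent test, and its p-values were not adjusted.

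The cytokine, macrophage, T and NK cell, fibroblast and matrix lists were called higher in CD109-/- tumours with camera's preset correlation. With an estimated correlation they were not called (0 of 39 lists, lowest adjusted p = 0.327), but on 2 degrees of freedom that form could hardly pass any list. Whether the list calls come from 1 of the CD109-/- arrays stays open for the 21 calls together, of which 15 stayed without replicate 1 and 11 without replicate 2. In the 5 lists called in all settings, both CD109-/- arrays lay above both CD109+/+ arrays. Their median shifts were at least 0.30 whichever array was left out. This argues against a single CD109-/- array setting the shift of these 5 lists, which were picked for keeping their calls. In contrast, the neutrophil shift was 0.06 without CD109-/- replicate 1 and the ciliated shift 0.06 without CD109-/- replicate 2. A lower share of tumour cells in the CD109-/- samples could raise the markers of all other cell types alike, and this stays open. A shift was taken as the difference between genotypes in the mean of the medians by array. Among the cell types compared, B and plasma cells at 0.25 ± 0.16 lay furthest from the T and NK shift of 0.68 ± 0.05 (SE), by 2.17 standard errors against a limit of 14.8. Muscle and alveolar type 2 markers were left out of this comparison. Their medians by array overlapped between genotypes. For muscle these were 0.21 and -0.09 in CD109+/+ and -0.03 and 0.06 in CD109-/- tumours, and for alveolar type 2 cells -0.08 and 0.06 against -0.07 and 0.16. The 4 arrays allow 3 splits of 2 against 2, too few for a share under 0.05. The genotype split was the 1 with most lists (21, highest other 17), while 2 of 3 splits gave at least its 1219 genes at an unadjusted p under 0.05, the highest other giving 1315 by setting both replicates 1 against both replicates 2 (with that number as a block the genotype gave 1898 genes and 18 lists).

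Xlr3b, Xlr4a and Xlr4b, the last chosen after its values were seen, lie on the X chromosome, and 1 of the CD109-/- arrays is from a male. The difference was not confined to the male array. The female CD109-/- array exceeded the higher CD109+/+ array by at least 1.86 on the log2 scale in all 3 genes, whereas the CD109+/+ arrays differed by at most 0.28. These genes were picked for low p or after their values were seen, which favours such a gap, so this is no independent test. A further Xlr4a probe gave a smaller difference of 1.26. Log2 signals of Xlr4b were -2.46 and -2.18 in CD109+/+ and -0.45 and -0.30 in CD109-/- tumours. Other causes, among them a difference in strain background or in cell composition between the lines, were not tested.

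Alleles carried along with the targeted locus might change its neighbours. Among the other genes named for the lowest p, only Pcolce2 and Mst1 also lay on chromosome 9, which carries Cd109. Of the 100 measured genes nearest to Cd109 by gene order, 12 had an unadjusted p under 0.05, or 12% against 7.38% of other genes (odds ratio 1.71, confidence interval 0.849 to 3.15, Fisher's exact p = 0.0839). The interval includes both no excess and a severalfold one, so the question stays open.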
